A study of Drosophila melanogaster with 2 samples.

How the data were processed

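Chromatin immunoprecipitation and sequencing was carried out on whole embryos of a Drosophila melanogaster line with GFP fused to scrt, with sonicated chromatin and a fragment size range of 200 to 800 bp per the labels. The 2 samples, biological replicates 3 and 4, form a single group, so the only comparison between samples is their agreement. Collection at 4 to 24 h was taken from the source description; an age field in the labels holds another value that is not a plausible age, and it was not used.

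The data are 4 lists of peaks in narrowPeak format on assembly dm6. Per the file listing deposited with each sample, peaks were called against control alignments for replicate 3, for replicate 4 and for their pooled alignments, and the optimal list was made from these by an IDR threshold. The peak caller, the aligner, the IDR threshold and the read depth are not given in the sources used here. Each of the first 3 lists holds 30000 peaks, most of them of fixed width (430 bp in the pooled list for 86.2% of peaks), and per the listing it includes background kept as IDR input. The 6407 optimal peaks are the 6407 pooled peaks of highest signal. The deposited signal of a peak is the authors' own enrichment value (193 to 10013 in the optimal list) and its scale is set within a list, so signals were compared only within a list and lists only by rank. The deposited −log10 q-value reached a ceiling of 4.02 for 81.3% of optimal peaks and was not used for ranking. The deposited summit offset gave the position of each summit.

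Genes and transcription start sites were taken from Ensembl release 115 for the same assembly (coordinates of Release 6), and 0 of 96407 peaks ran past a chromosome end. Summits within 500 bp of a TSS were called promoter, and the others were placed in order in the 5' UTR, coding exon, 3' UTR, non-coding exon, intron or intergenic sequence. Overlap of the leading peaks of the replicates was compared with 1000 circular shifts along each chromosome, and location with 1000 random placements on the same chromosomes. Sequence was searched on both strands within 100 bp of each summit and in a paired window 1000 bp away, on a side drawn with a fixed seed, and compared with the exact McNemar test. The 10 E-boxes and CAACAGGTG formed a family of 11 motifs and the 2080 6-mers another, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Signal with and without CAGGTG was compared by a permutation test of the medians with 100000 resamples. Gene lists (20, with 591 distinct genes, 7 matched through a synonym) were compared with other protein-coding genes in strata of length decile and TSS number (1, 2, or 3 and more) by an exact test, two-sided as double the smaller tail. Intervals on shares are Wilson 95% intervals. Intervals on odds ratios are exact binomial 95% intervals from the pairs in which only the summit window or only the paired window held the motif.

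The tests, the lists and the rule for named genes were fixed before the data were examined. The rule named scrt, the gene nearest to each of the 20 leading peaks, up to 4 bound members of highest signal and 2 unbound members per list, and the 10 enriched and 5 depleted 6-mers of largest odds ratio. Alternatives were peaks from a single replicate, the 3203 optimal peaks of highest signal, merging of summits within 500 bp, other windows, overlaps and gene assignments, random windows matched on GC content, and Fisher's exact test without strata. A comparison of location with the 10000 lowest-ranked pooled peaks was added after seeing the data.

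The procedures were tested on simulated data of the same size. For the overlap of leading peaks (6407 simulated peaks) a planted share of 60% was recovered as 61.2%, and for the promoter share 30.5% was recovered for an expected 30.5%. For the E-box share 21.1% was recovered for 21.6% with 0 other E-boxes called, and 0 of 2080 6-mers were called with none planted. The simulated summits for these sequence tests lay at random genome positions. Real summits lay more often at promoters and differed in GC content from their paired windows, so the simulation does not calibrate the calls made on them. For the gene lists, drawn over 13945 genes, 6 of 6 planted lists were called. Every member of a planted list was bound, so this does not show whether a weaker excess would be found. Of lists of random genes, 1% had p under 0.05 in the exact stratified test, against a nominal 5%, so the test was cautious there. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.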

Results

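Binding of scratch (scrt), a neuronal zinc-finger transcription factor of the Snail family, was profiled by chromatin immunoprecipitation and sequencing in whole Drosophila melanogaster embryos. The embryos were of mixed sex, were collected 4 to 24 h after laying, and came from a transgenic line that carries scrt fused at its C terminus to GFP, written scrt-GFP in the strain label and scrt-eGFP in the description. The labels list 2 biological replicates, numbered 3 and 4, which form a single group. A description in the labels calls both libraries input controls, whereas their antibody field names scrt and a separate control experiment is listed; they were treated here as scrt immunoprecipitations. The deposited files are lists of peaks on assembly dm6. Each replicate and their pool had a list of 30000 peaks, and a list thresholded by the irreproducible discovery rate (IDR), called the optimal list here, had 6407. Read depth is unknown, so no interval below covers sequencing depth; intervals on shares of peaks are Wilson 95% intervals and cover counting error only. The peak signal is the authors' own value and was used to rank peaks within a list.

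The strongest scrt-GFP peaks were the same sites in both replicates. The leading peak of the optimal list, at the promoter of bma (3L, 9927020 to 9927748) with a signal of 10013, ranked 1 in replicate 3 and 1 in replicate 4. The peaks at the promoters of Sox14, which encodes an HMG-box transcription factor, and brat, a tumour suppressor of dividing neuroblasts, ranked 2 and 5 in replicate 3 and 6 and 10 in replicate 4. All 20 leading optimal peaks lay within rank 35 in replicate 3 and rank 41 in replicate 4. Among the 6407 best peaks of replicate 3, 79.0% (95% interval 78.0 to 80.0) overlapped by at least 1 bp a peak among the 6407 best of replicate 4, and 77.0% did so in the reverse direction. Shifting the peaks along each chromosome gave 3.19% ± 0.272 (SD, 1000 shifts), with a maximum of 4.07% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Of the optimal peaks, 77.7% (4980) overlapped leading peaks of both replicates. That share was 99.1% at ranks 1 to 1281 and 29.5% at ranks 5126 to 6407, where peaks lie near the rank at which each replicate's leading peaks end. In the full lists of 30000 peaks, 97.2% of the optimal peaks at ranks 5126 to 6407 overlapped a peak of both replicates. The optimal list was chosen by IDR from these same replicates and ranked by the signal of their pool. The replicate ranks and shares of optimal peaks are therefore not an independent measure of agreement. The overlap of each replicate's own best peaks does not use that ranking. Across optimal peaks, which are not independent replicates, the Spearman correlation of the replicates' signals was 0.74. Within the 5 rank ranges it ran from -0.46 to 0.71, and the Pearson correlation of log10 signals from 0.10 to 0.80; the ranges were cut on the signal of the pool of both replicates, which itself shapes these values, so no agreement or disagreement is read from them.

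**Figure D1:**
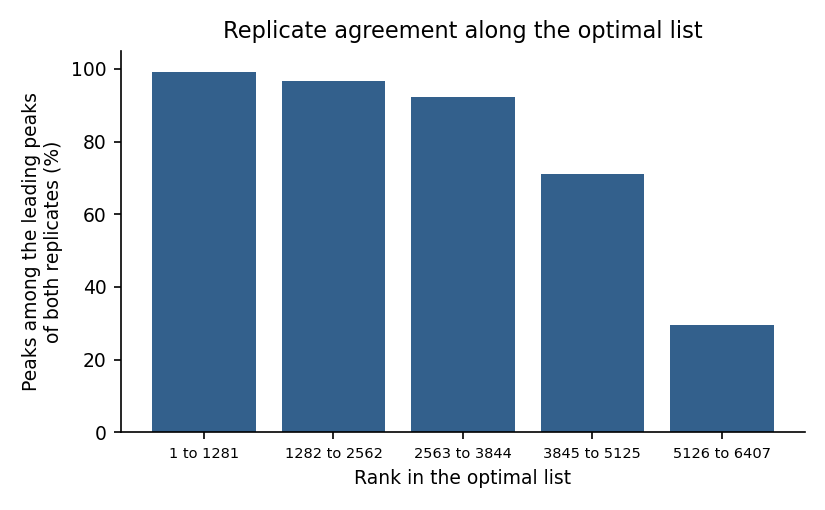
Share of optimal peaks (vertical axis, percent) that overlap the best-ranked peaks of both replicate 3 and replicate 4, by rank in the optimal list (horizontal axis; each bar holds 1281 or 1282 peaks). The share falls from 99.1% at ranks 1 to 1281 to 29.5% at ranks 5126 to 6407, next to the rank at which each replicate's leading peaks end. The optimal list was chosen by IDR from these same replicates, so the shares are not an independent measure of agreement.

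The tagged gene itself carried one of the stronger peaks. The promoter of scrt (FBgn0004880, 3L, 3983896 to 3994003, plus strand) had a peak at 3983020 to 3984100 with its summit 248 bp from the transcription start site (TSS) and a signal of 4878, rank 21 of 6407. It ranked 7 in replicate 3 and 68 in replicate 4. The neighbouring CG12605 (FBgn0035481, 3L, 3954251 to 3964771, minus strand), another Snail-family zinc-finger gene, had a peak of signal 6216 at 3964495 to 3965659, rank 7, in the intergenic sequence 520 bp from its TSS, and a second peak of signal 4384 at its promoter. These peaks overlap at their edges. Both matched the same peak of replicate 3, at rank 6, and separate peaks of replicate 4, at ranks 7 and 22. Within 30000 bp of scrt there were 26 optimal peaks, most of them intergenic and of signal under 1000. Some of them overlap a neighbour, so this is a count of peaks and not of separate sites. The 50000-bp window at 3L, 3950001 to 4000000, held 17 peaks, against a median of 2 over 2653 such windows. The fullest window, at tara on 3R (16200001 to 16250000), held 22 peaks.

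**Figure D2:**
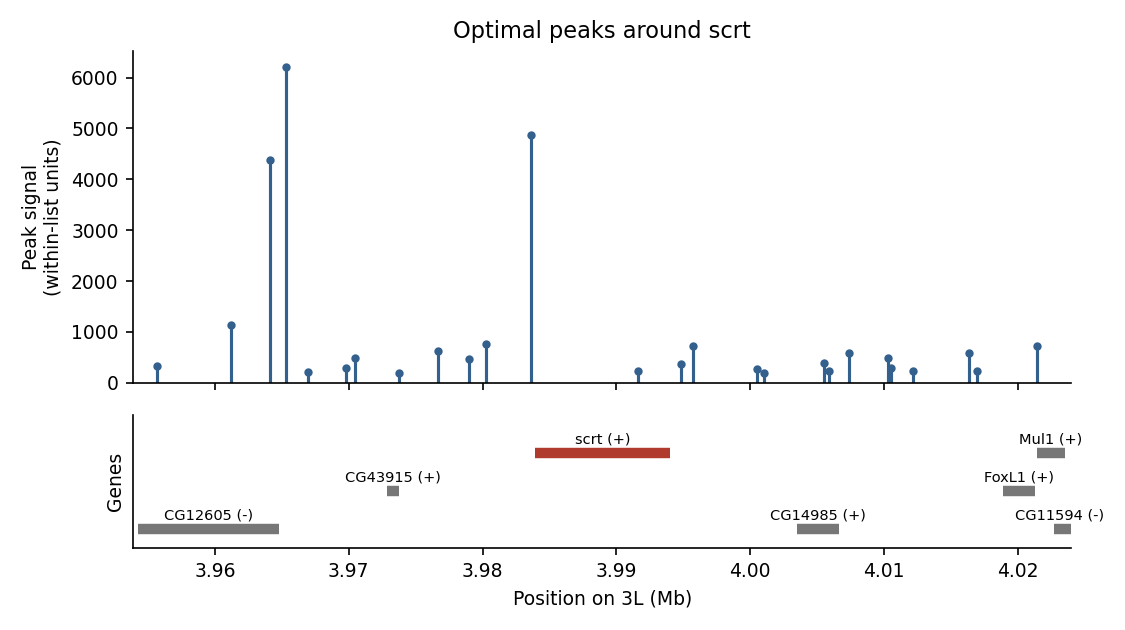
Map of the region around scrt on 3L (horizontal axis, dm6 position in Mb). Each line in the upper panel is an optimal peak, drawn at its summit with its signal as the height, and the lower panel shows protein-coding genes with their strand, scrt in red. The 3 tallest lines, of signal 4384, 6216 and 4878, lie at CG12605 and at the scrt promoter.

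Among the 20 leading peaks, named by the TSS nearest to each summit, were sites at genes for neuropeptide receptors and ion channels. The CNMaR gene, for the receptor of the neuropeptide CNMamide, had a promoter peak of signal 6493 at 3L, 9643598 to 9644275, inside fry. Dh44-R2, for a diuretic hormone receptor, had a promoter peak of 5264, and MsR2, for a myosuppressin receptor, one of 5018. The genes unc79 and unc80, which encode auxiliary subunits of a sodium leak channel, had peaks of 5146 at the promoter and 5640 in an intron. A peak of 5183 lay 1154 bp from the TSS of Ca-alpha1T, a T-type calcium channel gene, and a peak of 5562 lay 1086 bp from that of Fife, which encodes a presynaptic active zone protein. Other leading peaks were at cbt, a zinc-finger gene (7121, in an intron of ush), btsz (5414), the nucleotide-sugar transporter gene Ugalt (5470), Dlg5 (5058), the kinase gene Lrrk (4970), CG11050 (5797) and CG33169 (5445). A peak of 4892 was named by CG4004, whose TSS lay 4998 bp away. Its summit was outside CG4004, in a non-coding exon. The second-ranked peak, of 8224 at 2R, 16070555 to 16071470, was intergenic, with its nearest TSS, that of CG8405, 23535 bp away. In total, 12 of these 20 peaks were at promoters.

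Binding was concentrated at promoters and rare in coding sequence. Of the 6407 optimal summits, 3034 (47.4%) lay within 500 bp of an annotated TSS, against 13.6% ± 0.432 (SD) in 1000 random placements on the same chromosomes, a ratio of 3.48. Coding exons held 0.437% of summits, against 13.7% ± 0.431 at random, and 3' UTRs held 0.827%, against 4.40% ± 0.256. Introns held 36.1%, against 39.4% ± 0.627, and intergenic sequence 13.6%, against 27.3% ± 0.559. For each of these classes the two-sided permutation p was 0.002, the smallest that 1000 placements can give. Shares in the 5' UTR (0.827%, p = 0.643) and in non-coding exons (0.874%, p = 0.631) did not differ detectably from random in the same permutation test. Median signal was 369 at promoter peaks, 313 at intronic and 309 at intergenic peaks, and 451 at the 28 peaks in coding exons, of which 7 held CAGGTG (25%, 95% interval 12.7 to 43.4).

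The promoter share followed the rank of the peaks. Of the 500 best peaks of the pooled list, 65.2% were at promoters, and of ranks 4001 to 6407, 40.6%. The share was 14.7% at ranks 25001 to 30000, close to that of random placements. In the 10000 lowest-ranked pooled peaks, a comparison chosen after seeing the data, promoters held 15.3% and coding exons 0.88%. The low share of coding exons was thus shared by peaks below the threshold, although the optimal list was lower still (odds ratio 0.494, Fisher's exact test, adjusted p = 0.0011).

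**Figure D3:**
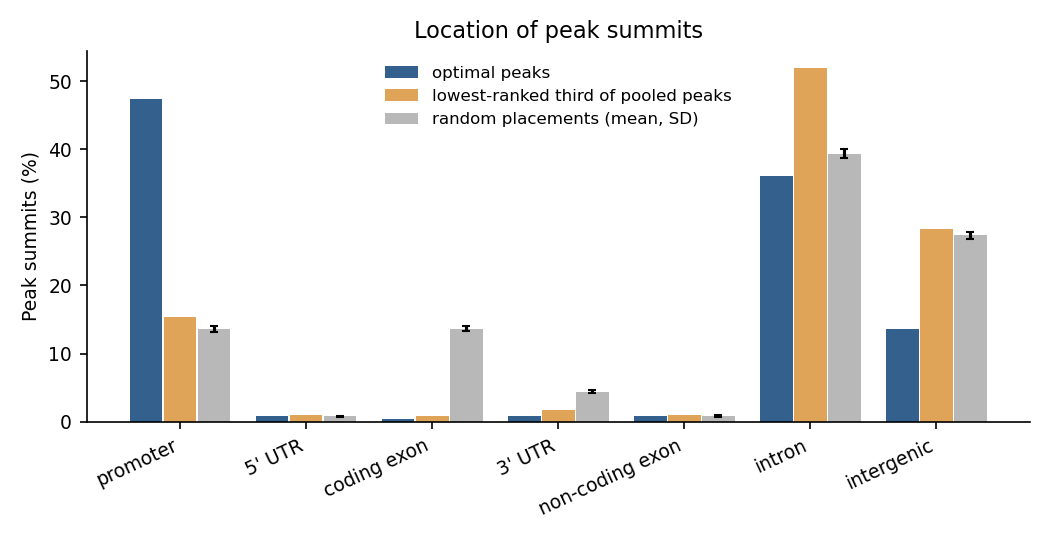
Share of peak summits (vertical axis, percent) in each annotated location (horizontal axis) for the optimal list, the 10000 lowest-ranked pooled peaks and random placements (mean and SD of 1000). Promoters hold 47.4% of optimal summits, against 15.3% of the low-ranked peaks and 13.6% of random placements.

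The sequence CAGGTG, the E-box that Snail-family zinc fingers are known to bind, was not enriched at optimal summits. It was present within 100 bp of 492 summits (7.68%, 95% interval 7.05 to 8.36), against 8.33% of paired windows centred 1000 bp away (odds ratio 0.915, exact McNemar test, adjusted p = 0.286 over 11 motifs). At promoter peaks it was less frequent than in the paired windows (exact test, 7.75% against 10.3%, adjusted p = 0.00258), and at peaks outside promoters the shares were 7.62% and 6.58% (adjusted p = 0.192). The summit shares were thus close in both settings and the paired shares were not. Whether the lower share at promoters comes from the summits or from the choice of paired windows was not tested. Promoter peaks alone were not compared with any other windows. Where CAGGTG was present, the copy nearest to the summit lay within 50 bp in 64.2% of peaks, against 51.0% for a single copy placed evenly in the window, a difference that was not tested. The longer CAACAGGTG was more frequent at summits, at 1.75% (1.45 to 2.10) against 0.375% (odds ratio 4.67, exact McNemar test, adjusted p = 9.54e-14). Its odds ratio was 6.70 outside promoters and 3.21 at promoters. Of the 20 leading peaks, those at CNMaR and unc80 held it.

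Other E-boxes also differed between summits and paired windows. CAGCTG was found at 12.6% of summits against 9.02% (odds ratio 1.46, exact McNemar test, adjusted p = 3.68e-10). Its share at promoter peaks was 16.5% against 9.59%, and outside promoters it was 9.07% against 8.51% (exact test, adjusted p = 0.483). In the same exact test, CAAGTG was found at 15.4% against 13.1% (adjusted p = 0.000603), and CAGATG (6.54% against 8.24%) and CAATTG (7.37% against 8.52%) were less frequent at summits (adjusted p = 0.000778 and 0.0379). With windows of 200 bp on each side of the summit, CAGGTG was less frequent at summits, at 13.7% against 15.7% (exact test, adjusted p = 0.00233). Against random windows matched on GC content, CAATTG no longer passed (Fisher's exact test, adjusted p = 0.127), while CACGTG (3.43% against 2.59%, adjusted p = 0.0134) and CAACTG (13.2% against 11.8%, adjusted p = 0.0455) were more frequent at summits.

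**Figure D4:**
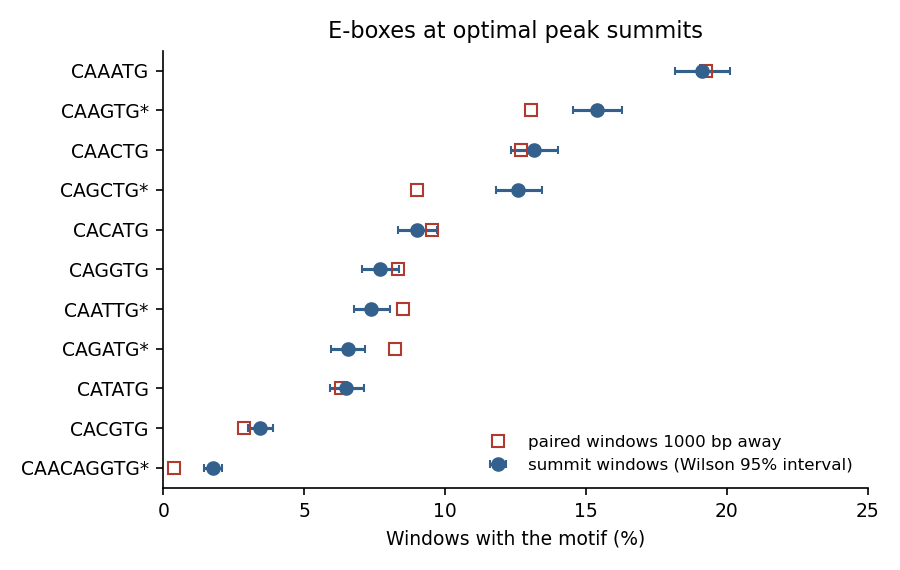
Share of windows with each E-box (horizontal axis, percent) within 100 bp of optimal summits (filled circles, Wilson 95% intervals) and in paired windows 1000 bp away (open squares). Asterisks mark adjusted p under 0.05; CAACAGGTG (1.75% against 0.375%), CAGCTG and CAAGTG are higher at summits, and CAGGTG is not.

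Of the 2080 possible 6-mers, 936 differed in frequency between summits and paired windows, 343 higher and 593 lower at summits (exact McNemar test, adjusted p under 0.05). GCAACA was the most enriched, at 31.1% of summits against 16.5% (odds ratio 2.31, exact test, adjusted p = 4.06e-81). CAACAG (24.7% against 12.4%), AACAGG (14.4% against 8.12%) and ACAGGT (9.68% against 5.37%) lie within CAACAGGT, which shares CAACA with GCAACA, and ACAAGT was at 18.0% against 10.4%. Also among the 10 most enriched were ACACTG (14.95% against 7.05%), CGATAG (7.16% against 4.07%), GAGAGA (14.3% against 8.46%), ACTAGT (3.29% against 1.84%) and AGTGTA (12.6% against 7.38%). The 5 most depleted, GATCCC, CGGATC, CGATCC, AGGATC and GGATCC, all hold GATC, with odds ratios of 0.389 to 0.408. The median GC content was 39.8% in summit windows and 42.3% in paired windows; against random windows matched on GC content, 889 6-mers differed, 600 of them among the 936.

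Peaks with CAGGTG had slightly higher signal. The median was 357 in the 492 peaks with it and 331 in the 5915 without, a difference of 26.4 (permutation test, 100000 resamples, two-sided p = 0.0161; peaks are not replicates). The distributions overlapped widely, with quartiles of 254 and 707 against 243 and 557. Of the 492 peaks, 112 held the longer CAACAGGTG, which contains CAGGTG. The difference was not computed without them, so it cannot be assigned to CAGGTG alone. Among peaks outside promoters the difference was 20.1 and did not pass the threshold (permutation p = 0.13). It was 49.9 with windows of 50 bp and 100.6 among the 3203 optimal peaks of highest signal (permutation p = 0.00096 and 0.00022).

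Ribosomal protein genes were bound more often than matched genes, and chemoreceptor genes less often. A gene was called bound if an optimal summit lay within 1000 bp of any of its TSSs, which held for 3570 of 13945 protein-coding genes (25.6%). Genes were matched on length and TSS number only, and not on expression or chromatin state in the embryo. An excess or deficit therefore does not by itself show a preference of scrt-GFP for a class of genes. Of 92 ribosomal protein genes 76 were bound, against 21.9 expected from genes of like length and TSS number (3.47-fold, exact stratified test, adjusted p = 2.20e-35 over 20 lists). Their highest signals were 2940 at RpL34b, 1874 at RpL7-like, 1647 at RpS27 and 1500 at RpL7, while RpL10Aa and RpL15 were unbound. RpS27 and RpL7 ranked 548 and 652 in replicate 3 but 158 and 197 in replicate 4. RpL34b and RpL7-like went the other way, at 62 and 179 against 136 and 345. The split was not even across these genes. Among bound RpL genes taken alphabetically from RpL10 to RpL4, only RpL10, RpL23, RpL34a, RpL34b and RpL36 ranked better in replicate 3. The bound RpL14 and RpL35 had no overlapping peak in the replicate 3 list. The list ratio, which counts a gene only as bound or not, was 3.38 with replicate 3 alone and 3.20 with replicate 4 alone. Of 179 chemoreceptor genes, which encode odorant, gustatory and ionotropic receptors, 6 were bound against 35.0 expected (0.171-fold, exact test, adjusted p = 7.30e-10). Those with the strongest peaks were Gr32a (2403), Ir75c (880), Gr28b (461) and Or88a (428), and Gr10a and Gr10b were unbound. The chemoreceptor ratio was 0.0966 with a TSS window of 500 bp and 0.449 when each peak was given to the nearest TSS at any distance (exact test, adjusted p = 9.55e-11 and 0.0011).

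None of the 8 Hox genes was bound at a TSS, lab and pb among them, against 4.28 expected (adjusted p = 0.0207 in the exact stratified test). That call held under 3 of 8 alternative settings, and when each peak was given to the gene with the nearest TSS at any distance the ratio was 0.991 (exact test, adjusted p = 1). Of 23 testis-specific genes, among them bam and can, 0 were bound against 4.09 expected (adjusted p = 0.1; 0.0111 with Fisher's exact test without strata). The exact test took the genes of a list as separate draws. Hox genes lie in clusters on 3R, and chemoreceptor genes such as Gr10a and Gr10b lie side by side. The p-values of these lists may therefore be too small.

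**Figure D5:**
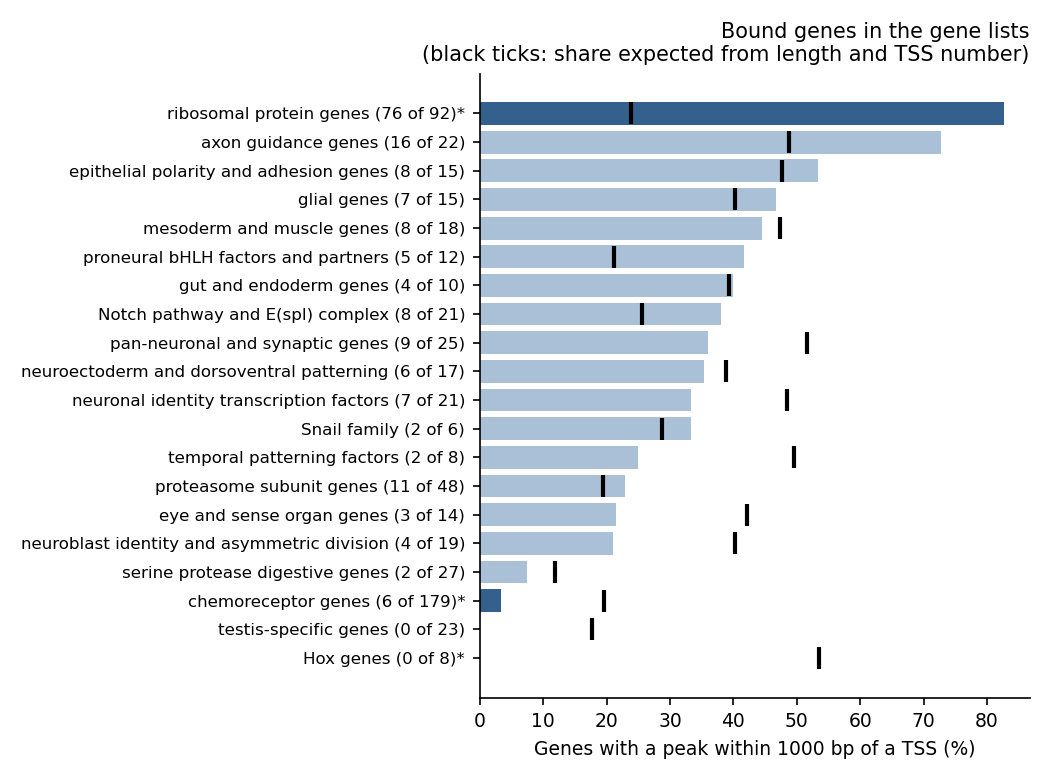
Share of genes (horizontal axis, percent) with an optimal peak within 1000 bp of a TSS in each gene list, with the bound and total numbers in parentheses and the share expected from gene length and TSS number as a vertical tick. Dark bars and asterisks mark adjusted p under 0.05; 76 of 92 ribosomal protein genes, 6 of 179 chemoreceptor genes and 0 of 8 Hox genes were bound.

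No list of nervous system genes passed the test, although single members had strong peaks. Axon guidance genes came closest, with 16 of 22 bound against 10.7 expected (1.49-fold, exact stratified test, adjusted p = 0.14). They included the Slit receptor gene robo2 (signal 4563), the cell-surface receptor gene Dscam1 (3227), Fas3 (1049) and trio (771), while robo1 and NetA were unbound. This list passed with a TSS window of 500 bp (adjusted p = 0.0476) and with Fisher's exact test without strata (adjusted p = 6.39e-05). Of 25 pan-neuronal and synaptic genes 9 were bound against 12.9 expected (exact test, adjusted p = 0.372), with elav, a neuronal RNA-binding protein gene, at 2224, Csp at 824, Vmat at 739 and Syx1A at 370, and with Rbp9 and nSyb unbound.

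Among regulators of neural fate, 5 of 12 proneural bHLH genes and partners were bound against 2.54 expected. They were led by dimm, a regulator of neuroendocrine cells (2276), emc (560), tap (457.9) and Oli (255.4), and ac and sc were unbound. Of 19 neuroblast genes 4 were bound against 7.64 expected: brat (6240), numb (913), aPKC (659) and scrib (244), with dpn and ase unbound. The temporal patterning factors had 2 of 8 bound, hb (279) and grh (222), with Kr and nub unbound. Of 21 Notch pathway genes 8 were bound, with gro, a corepressor gene, at 1092, E(spl)m3-HLH at 759, neur at 712 and hry at 372, and with N and Delta unbound. Of 21 neuronal identity factors 7 were bound against 10.2 expected, with Lim1 at 522, lola at 426, chinmo at 418 and tup at 336, and with eve and ftz unbound. The Snail family had 2 of 6 bound, CG12605 and scrt, with sna and esg unbound. None of these 6 lists passed the exact stratified test, with adjusted p of 0.372 or more.

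Lists of other tissues did not differ detectably from matched genes either. Of 15 glial genes 7 were bound, with moody, a blood-brain barrier receptor gene, at 1372, Gs2 at 773, nrv2 at 418 and pnt at 390, and with repo and gcm unbound. Of 18 mesoderm and muscle genes 8 were bound, with the muscle regulator Mef2 at 1111, Tm1 at 790, tin at 644 and sls at 504, and with twi and bap unbound. Of 15 epithelial polarity genes 8 were bound, led by aPKC (659), par-6 (581), dlg1 (544) and crb (532), with shg and baz unbound. Of 17 neuroectoderm and dorsoventral patterning genes 6 were bound, led by spi (951), vnd (691), brk (560) and Egfr (238), with sim and rho unbound. The gut and endoderm list had 4 of 10 bound, fkh, a forkhead gene, at 1394, bowl at 809, GATAe at 213 and cad at 209.6, with srp and byn unbound. The eye and sense organ list had 3 of 14 bound, so (310), phyl (231) and ey (194), with toy and eya unbound. Of 48 proteasome subunit genes 11 were bound, led by Prosbeta5 (2922), Rpt3R (1467), Prosbeta1 (677) and Rpn3 (417), with Prosalpha1 and Prosalpha1R unbound. Of 27 digestive serine protease genes 2 were bound, Jon25Bi (561) and Jon25Biii (195), with Jon25Bii and Jon44E among the unbound. No list in this paragraph passed the exact stratified test, with adjusted p of 0.372 or more. With the 6407 best peaks of replicate 3 alone, the neuronal identity and the eye and sense organ lists passed as bound less often than matched genes (exact test, adjusted p = 0.0499 for each).

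Peak density was similar on the large chromosome arms and lower on chromosome 4. The X carried 16.5% (15.7 to 17.5) of the optimal peaks on the 5 large arms, against 17.0% of their protein-coding TSSs (exact binomial test, two-sided p = 0.342). Measured against arm length, of which the X makes up 17.8%, the share was lower (exact binomial p = 0.0107). The large arms had 44.9 to 50.7 peaks per Mb, and chromosome 4, which is largely heterochromatic, had 18 peaks or 13.4 per Mb. Per 100 protein-coding TSSs, chromosome 4 had 12.7 peaks and the large arms 29.8 to 36.1. The difference for chromosome 4 was not tested, and the replicates differed there, with 206 peaks in the full list of replicate 3 and 65 in that of replicate 4.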

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

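The tests of CAACAAGT and CAACAGGT in this part were chosen after the 6-mer results had been seen. The pooled peaks ranked below the optimal list, for which the report gives location but no comparison of sequence, also held CAACAGGTG more often than their paired windows. It was present at 0.670% of these 23593 summits (158 peaks, 95% interval 0.573 to 0.782) against 0.254% of the paired windows (odds ratio 2.66, exact McNemar test, p = 1.85e-11). At ranks 6408 to 10000 the shares were 1.00% and 0.167%, and at ranks 25001 to 30000 they were 0.44% and 0.28%.

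The pattern behind this was a longer word at summits where CAGGTG alone was not enriched. On 2L and 2R the most over-represented 8-mer was CAACAAGT, at 196 summits against 24 paired windows. CAACAGGT, at 106 against 19, came lower in that ranking. Between them were AGCAACAG (175 against 35), GCAACAGG (118 against 18), GCAACAAG (136 against 28) and AACAAGTG (119 against 25). On 3L, 3R and X, which were not used to rank the 8-mers, 11.3% of summits held CAACAAGT or CAACAGGT against 1.95% of paired windows. The odds ratio was 6.33 (4.91 to 8.26), which argues against a word picked by chance. However, these arms were not wholly unseen. The 6-mers inside the words had been tested on all arms, and so had CAACAGGTG, which contains CAACAGGT. For CAACAAGT alone the odds ratio on 3L, 3R and X was 5.31 (3.93 to 7.32). The same letters in reversed order, TGAACAAC or TGGACAAC, had an odds ratio of 0.724 (0.515 to 1.01), which argues against base composition. A hypothesis that stays open is that scrt-GFP, or a factor bound with it, may recognise this longer word; the design holds no other group, so no biological explanation was tested.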

How the results depend on the processing

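Replicate overlap and the promoter share kept their direction and their call under each alternative run. Replicate overlap ranged from 62.3% to 78.7%, the promoter share from 33.5% to 57.5%, and the count of differing 6-mers from 678 to 961, with 600 to 863 of the 936 shared. The number of gene lists called ranged from 2 to 5, and the lists differed: the Hox call was lost under 5 alternatives and the axon guidance list gained one under 2. Leaving out each replicate in turn gave promoter shares of 45.6% and 50.1%, CAGGTG shares of 7.66% and 8.12%, 6-mer counts of 936 and 961, signal differences of 14.3 and 26.8 on each replicate's own scale, 3 and 5 gene lists, and X shares of 16.1% and 16.9%. The rise to 5 lists came with replicate 3 alone. The direction for CAGGTG was not stable. Its share was above the comparison windows with replicate 3 alone (8.12% against 8.08%), in the 3203 peaks of highest signal (8.46% against 8.21%), with 50 bp windows (4.79% against 4.34%), against windows matched on GC content (7.68% against 7.10%) and outside promoters (7.62% against 6.58%), without passing the threshold. With 200 bp windows it was below them past the threshold (13.7% against 15.7%); the adjusted p ran from 0.00233 to 0.987. The signal difference with CAGGTG was 20.1 outside promoters, where it lost its call, and reached 100.6 in the 3203 peaks of highest signal. The X share of 16.5% passed the threshold against arm length. Of the values for single lists, 125 kept direction and call, 5 gained a call, 5 lost one and 25 changed direction with no call on either side. Without replicate 3 the ratios that changed direction were 0.945 for glial (1.19 without replicate 4, direction kept), 0.943 for epithelial (1.16, kept) and 1.16 for neuroectoderm genes (0.625, kept), and for gut genes both did, at 0.957 and 0.521. In the 3203 peaks of highest signal they were 0.802 for gut and 0.865 for proteasome genes. Over gene bodies they were 0.947 for the Snail family, 0.990 for epithelial, 1.32 for neuroectoderm and 0.827 for gut genes. With the nearest TSS they were 1.15 for temporal factors, 1.02 for neuronal identity, 1.19 for mesoderm, 1.66 for neuroectoderm and 0.690 for proteasome genes. With a TSS window of 500 bp they were 0.966 for glial, 1.08 for mesoderm, 0.966 for epithelial and 0.896 for gut genes. Without strata they were 1.41 for pan-neuronal, 1.30 for neuronal identity, 1.74 for mesoderm, 1.38 for neuroectoderm and 0.895 for proteasome genes. The cause was not tested for any of these changes. Read depth is unknown, and the fixed 30000 peaks per replicate list hide any difference in depth.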

Other observations

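The tests of TATCGATA, GAGAGA, ACACTG and CAGCTG, those of words along the ranking, and the comparison with other peak-rich windows were chosen after the results had been seen. Of the enriched words compared by location, TATCGATA differed most between promoters and other sites. TATCGATA, the element that the factor DREF binds at many housekeeping promoters, was at 4.94% of promoter summits against 0.461% of paired windows (odds ratio 10.7, exact McNemar test, p = 6.22e-30) but at 0.208% against 0.504% outside promoters (p = 0.0639); the shares at and outside promoters differed (Fisher's exact test, p = 1.88e-40). CAACAAGT or CAACAGGT was at 12.99% of summits outside promoters and 10.4% at promoters (Fisher's exact test, p = 0.00145). Of the pair, CAACAAGT alone was at 8.36% and 6.23% (p = 0.00111 in the same exact test) and CAACAGGT alone at 4.77% and 4.35% (p = 0.437). GCAACA was at 31.9% and 30.2% (same exact test, p = 0.137). GAGAGA, which GAGA factor binds, was at 14.9% and 13.5% (same exact test, p = 0.133), and ACACTG at 14.2% and 15.8% (p = 0.0681).

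Peak strength went with the longer word. CAACAAGT or CAACAGGT was at 25.6% (22.0 to 29.6) of the 500 best peaks, 8.27% (7.23 to 9.44) at ranks 4001 to 6407 and 3.02% (2.58 to 3.53) at ranks 25001 to 30000, against 1.60%, 2.29% and 1.64% of the paired windows. In the optimal list, the 754 peaks with it had a median signal of 445 against 325 without (permutation p = 1e-05, the smallest that 100000 resamples can give). The copy nearest to the summit was within 25 bp in 57.2% of these peaks, against 25.8% for an even spread over the window. The genes with the most optimal peaks in their body and 1000 bp around it were shn, which encodes a zinc-finger regulator of Dpp signalling, and sick, with 18 each. On chromosome 4, the list of replicate 3 had 206 peaks and that of replicate 4 had 65.

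The peaks at ribosomal protein genes lay a median of 23.5 bp from the gene's own TSS. Of the 76 bound genes, 89.5% (80.6 to 94.6) were the gene nearest to their best peak, which argues against peaks of neighbouring genes. CAACAAGT or CAACAGGT was at 2.63% (0.725 to 9.10) of these 76 peaks, below the 10.6% of other promoter peaks (Fisher's exact test, p = 0.0207) and near the 2.13% of paired windows, so recovery of promoter DNA without the word may account for them but is not settled by 2 peaks. TATCGATA was at 25% of them against 4.43% of other promoter peaks (Fisher's exact test, p = 1.69e-09). In the same exact test, GAGAGA (1.32% against 13.9%, p = 0.000277) and CAGCTG (7.89% against 16.7%, p = 0.0411) were rarer at these peaks, and ACACTG was at 23.7% against 15.6% (p = 0.0776). No biological explanation was tested.

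The 26 optimal peaks around scrt exceeded the number in 99.98% of 13221 windows of the same 70108 bp on the large arms. These windows overlap one another and include some over the scrt region itself. If the transgene adds copies of this segment, low-ranked peaks should be dense there too, and there were 35 peaks ranked below the optimal list, against a median of 12 and a 95th percentile of 28 over all windows. However, of the 100 overlapping windows with at least 15 optimal peaks, 29% had as many or more. Some of these windows also cover the scrt region, so this share is not independent of it. Extra copies and a generally peak-rich region therefore cannot be told apart. Of the cluster's 23 peaks outside promoters, 4.35% (0.772 to 21.0) held CAACAAGT or CAACAGGT, against 13.04% of other such peaks (Fisher's exact test, p = 0.349), which with 1 peak leaves open whether the cluster lacks the word; GCAACA was present at 12 of the 26 peaks, against 31.1% of all optimal summits (not tested). Binding of scrt-GFP to its own locus may also account for the cluster and was not tested.

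The neuropeptide receptor and ion channel genes at the leading peaks raised the hypothesis that these classes may be bound more often in general. Without the genes of the 20 leading peaks, 16 of 33 neuropeptide and peptide hormone receptor genes were bound against 13.5 expected (ratio 1.19, exact stratified test, p = 0.458, adjusted p = 0.659). Their strongest peaks were at CCHa2-R (2217), sNPF-R (1835) and Dh44-R1 (1661). Of 23 voltage-gated and leak channel genes 10 were bound against 11.5 expected (ratio 0.870, p = 0.659 in the same exact test), with the potassium channel genes Elk (3744) and Sh (1601) among them. Neither class differed detectably from matched genes.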
